A study of Oryza sativa with 24 samples.

How the data were processed

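RNA was measured by sequencing in developing inflorescences of rice (Oryza sativa, the line named 9522 in the labels). Inflorescences of the tap mutant and of the wild type (WT) were taken at lengths of 2 mm and 3 mm from plants kept at a high or a low temperature. Genotype, length and temperature give 8 groups, and each group has 3 libraries, 24 in all. The degrees of each temperature, the duration of the treatment and the locus that carries the mutation are not given in the sources used here. The sample titles name the mutant ild, while the genotype field names it tap, and tap is used throughout.

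Per the labels' protocols, RNA was extracted with an RNeasy kit and libraries were made with a SMARTER mRNA-Seq kit. Per the submitters' processing notes, Trimmomatic, HISAT2 and HTSeq were used and the genome build was IRGSP-1.0; no versions, annotation release or strand setting are given in the sources used here. The values the authors deposited are raw read counts per locus, as whole numbers, in 1 table. Without a stated strand setting, reads of overlapping and antisense loci cannot be told apart, and reads of near-identical loci may have been divided between copies.

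The table holds 26480 loci. The smallest sum of a locus over the 12 low-temperature libraries was 10 counts, while 723 loci had 0 counts in all 12 high-temperature libraries and 0 loci had 0 counts in all 12 low-temperature libraries. The deposited rows had therefore been chosen on the low-temperature libraries, so a locus transcribed at high temperature alone is missing from the table, and counts of rises and falls with temperature are not on an equal footing. A further 70 loci carry no value in the high-temperature columns. They held at most 0.22% of the reads of any low-temperature library and were left out of the models over all 24 libraries, which left 26410 loci. The columns of the high- and low-temperature libraries are also named in different styles. The high-temperature columns of the mutant carry the name iHT rather than ild and were assigned to tap by inference, because the other high-temperature columns are named WT. No label says whether the 2 sets were grown, sequenced or counted together.

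Library totals ran from 19819257 to 21305381 counts. The 10 most abundant loci took 2.8% to 4.5% of a library. Differential expression was tested with edgeR 4.0.16 (limma 3.58.1) in R 4.3.3 by the quasi-likelihood F test with robust dispersion estimates, TMM normalization and the default filterByExpr filter, which left 23658 loci. A single model with a mean per group over all 24 libraries had 16 residual degrees of freedom, and 15 contrasts were taken from it. P-values were adjusted within each contrast by the Benjamini-Hochberg method, and a locus was called at an adjusted p under 0.05. Interaction values are the log2 difference of tap and WT in the first condition minus that in the second. Expression levels are library-size-scaled counts (CPM) with TMM-scaled library sizes, given as mean ± SD over 3 libraries; the principal components used log2 CPM with a prior count of 2. No label says whether replicates came from separate plants, so p-values measure only the spread between these samples, which may be technical.

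Where all 3 libraries of a group had 0 counts, a fold is a lower bound against a floor of 3 counts over the group. Where a group held 1 to 3 counts, the ratio is given with its exact 95% binomial counting interval. Such bounds and intervals cover counting error only.

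The files do not pair the locus identifiers with gene names. The table of RefSeq genes provided for the species matched 0 of the 26480 identifiers, so loci are given by identifier and no gene function is stated. Gene lists for panicle and flower development, hormones, heat response, other tissues and RNA quality had been fixed before the data were examined. None of them could be matched to the table, so no list was tested. The rule for named loci, also fixed before the data were examined, asked for an adjusted p under 0.05, a mean of at least 5 CPM in a compared group, library values that did not overlap between 2 compared groups, an informative annotation, and the largest log2 changes in each direction. The annotation criterion could not be applied, and the number was reduced to 2 loci per direction and comparison. Chromosomes are read from the identifiers, which number loci along each chromosome.

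The model was checked on counts simulated from the group means, the library sizes and a single dispersion per locus for all libraries. In 2 mm tap inflorescences at high temperature 200 of 23658 loci were changed, drawn from loci above a minimum level in WT there. For tap against WT at 2 mm and high temperature, 53.7% of the loci changed 1.5-fold, 79.1% of those changed 2-fold and 97% of those changed 4-fold were recovered, and 10 unchanged loci were called. For the genotype by temperature interaction at 2 mm the shares were 20.9%, 70.1% and 87.9%, with 3 unchanged loci called. The simulated libraries had the same spread at each temperature. In the real data the median SE of tap against WT, in models of each temperature alone, was 0.138 at high and 0.094 at low temperature. The simulated shares therefore do not cover a spread that differs between temperatures. The real data gave 8752 and 6344 called loci in these comparisons, far more than the 200 changed here. An adjusted p depends on how many loci change, so the shares and unchanged calls do not carry over to the real comparisons.

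Alternatives fixed beforehand were RLE size factors, DESeq2 1.42.0, no filter on low counts, a model of the compared libraries alone, a replicate block, a test against a 1.5-fold change, and leaving out each library in turn. Alternatives chosen after seeing the data were a minimum of 10 counts at high temperature for the temperature comparisons, the removal of 2 chromosome segments for the genotype comparisons, and a minimum mean of 5 CPM. Within groups, the 24 pairs of libraries differed by more than sampling noise, with a chi-square of 3.31 to 29.22 per degree of freedom, so no library was taken for a second copy of another. Separate preparations of 1 sample would differ by more than that noise too.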

Results

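Transcript counts were obtained from 24 inflorescence libraries of rice, covering the tap mutant and WT, 2 lengths (2 mm and 3 mm) and 2 temperatures, with 3 libraries per group. The series title names TAP as a locus required for panicle and spikelet development at high temperature, and the comparisons below ask how the mutant differs from WT at each temperature, whether that difference depends on temperature, and how each genotype responds to temperature and differs between lengths. Library totals were 19819257 to 21305381 counts at high temperature and 20368521 to 20948603 at low temperature, so depth was similar in all groups. At that depth, 2215 to 2937 loci had 0 counts in a high-temperature library and 738 to 976 in a low-temperature library. The TMM factors did not overlap, at 0.905 to 0.978 and 1.033 to 1.075. Temperature, the choice of rows and separate processing of the 2 sets cannot be told apart as sources of these differences. The libraries separated first by temperature set and then by genotype. On the first of these axes, too, separate processing of the sets cannot be told apart from temperature. The first principal component held 70.6% of the variance and placed the 12 high-temperature libraries apart from the 12 low-temperature libraries, and the second held 11.3% and placed all tap libraries apart from all WT libraries.

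**Figure D1:**
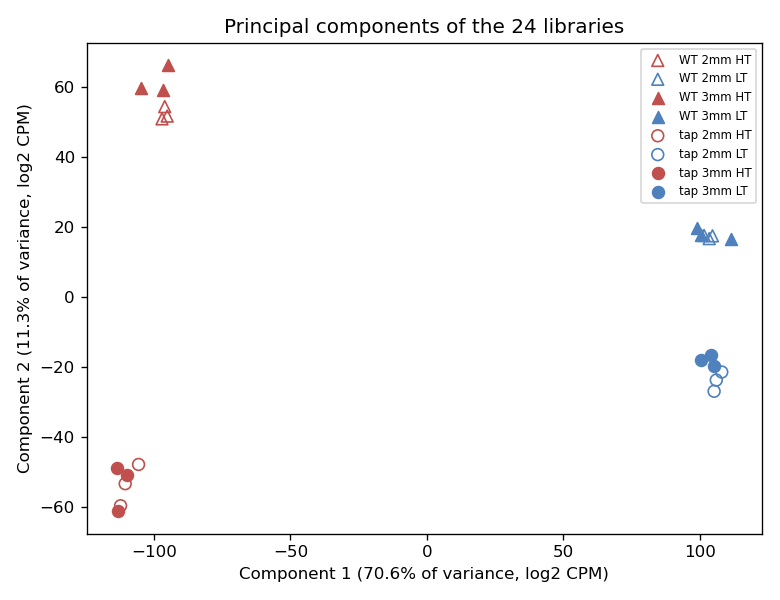
Principal components 1 (horizontal, 70.6% of the variance of log2 CPM) and 2 (vertical, 11.3%) of the 24 libraries, each point being 1 library, with color for temperature (red high, blue low), shape for genotype (circle tap, triangle WT) and filled symbols for 3 mm. The temperatures lie on opposite sides of component 1, and tap and WT lie on opposite sides of component 2, farther apart at high temperature.

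At high temperature, tap and WT inflorescences of 2 mm differed at 8752 of 23658 tested loci, of which 4347 were higher and 4405 lower in tap. Among changes of more than 2-fold, rises outnumbered falls, with 1374 loci higher and 779 lower. LOC_Os07g36290 on chromosome 7 reached 46.3 ± 3.91 CPM (SD, n = 3) in tap and had 0 counts in all 3 WT libraries, which made it at least 908-fold higher. LOC_Os08g05970 on chromosome 8 stood at 13.2 ± 2.78 CPM in tap against 0 counts in WT and was at least 258-fold higher. In the other direction, LOC_Os01g06510 on chromosome 1 had 7.01 ± 0.119 CPM in WT and 0 counts in tap, at least 137-fold lower, and LOC_Os03g45220 on chromosome 3 had 6.29 ± 0.966 CPM in WT and 0 counts in tap, at least 122-fold lower. There were 53 loci with at least 10 counts in every tap library and at most 1 in every WT library, and 19 with the opposite pattern. The test against a 1.5-fold change called 1650 loci, 1048 higher and 602 lower.

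Inflorescences of 3 mm at high temperature gave a difference of similar extent, with 8776 loci called, 4555 higher and 4221 lower in tap. LOC_Os07g36290 was again higher, at 53.5 ± 2.98 CPM (n = 3) in tap and 0 counts in WT, at least 1040-fold higher. LOC_Os08g05960, a locus numbered next to LOC_Os08g05970, was at 38.2 ± 4.81 CPM in tap and 0 counts in WT, at least 739-fold higher. LOC_Os01g06510 fell from 5.7 ± 1.02 CPM in WT to 0 counts in tap, at least 110-fold lower, and LOC_Os09g26520 on chromosome 9 fell from 19.1 ± 1.99 CPM to 2 counts in 3 libraries, a ratio of 551 with a 95% counting interval of 152 to 4550. The on and off loci numbered 53 for tap and 15 for WT. The 2 lengths shared 2985 of the higher loci, where independent lists would share 837, and 2755 of the lower loci, where they would share 785.9. Opposite calls were rare, with 45 loci against 1623.7 for independent lists. The test against a 1.5-fold change called 2033 loci.

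At low temperature the difference between tap and WT was smaller in number. Inflorescences of 2 mm had 3542 called loci, 1814 higher and 1728 lower in tap, and those of 3 mm had 2768, of which 1306 were higher and 1462 lower. The 4 loci named at 2 mm all lie near the start of the numbering of chromosome 1. LOC_Os01g05510 had 8.8 ± 1.48 CPM (n = 3) in tap at 2 mm and 8.19 ± 0.855 CPM at 3 mm, with 0 counts in WT at each length, which made it at least 194-fold and at least 176-fold higher. LOC_Os01g05530 had 21.9 ± 2.83 CPM in tap at 2 mm and 2 counts in WT, a ratio of 724 (95% counting interval 200 to 5980), and at 3 mm the ratio was 412 (141 to 2000). LOC_Os01g04430 went the other way, with 17.2 ± 0.786 CPM in WT at 2 mm and 1 count in tap, a ratio of 1110 (199 to 43900), and with a ratio of 577 (159 to 4770) at 3 mm. LOC_Os01g05289 had 23.6 ± 1.53 CPM in WT and 2 counts in tap at 2 mm, a ratio of 763 (211 to 6310). At 3 mm, LOC_Os04g32080 on chromosome 4 had 22.9 ± 2.33 CPM in WT and 3 counts in tap, a ratio of 493 (168 to 2390).

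The lengths shared 962 higher and 978 lower loci at low temperature, where independent lists would share 100.1 and 106.8, and 1 locus was called in opposite directions. Models of the 6 compared libraries alone called 5611 loci at low and 7069 at high temperature at 2 mm, and 3570 and 6579 at 3 mm. The gap between temperatures was thus smaller than in the model of all libraries. In models of each temperature alone, the median SE of the log2 difference of tap and WT over 16217 loci of at least 5 CPM was 0.094 at low and 0.138 at high temperature. At 3 mm the count fell to 1791 without replicate 3 of tap and to 1793 without replicate 1 of WT. The test against a 1.5-fold change called 589 loci at 2 mm and 434 at 3 mm.

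**Figure D2:**
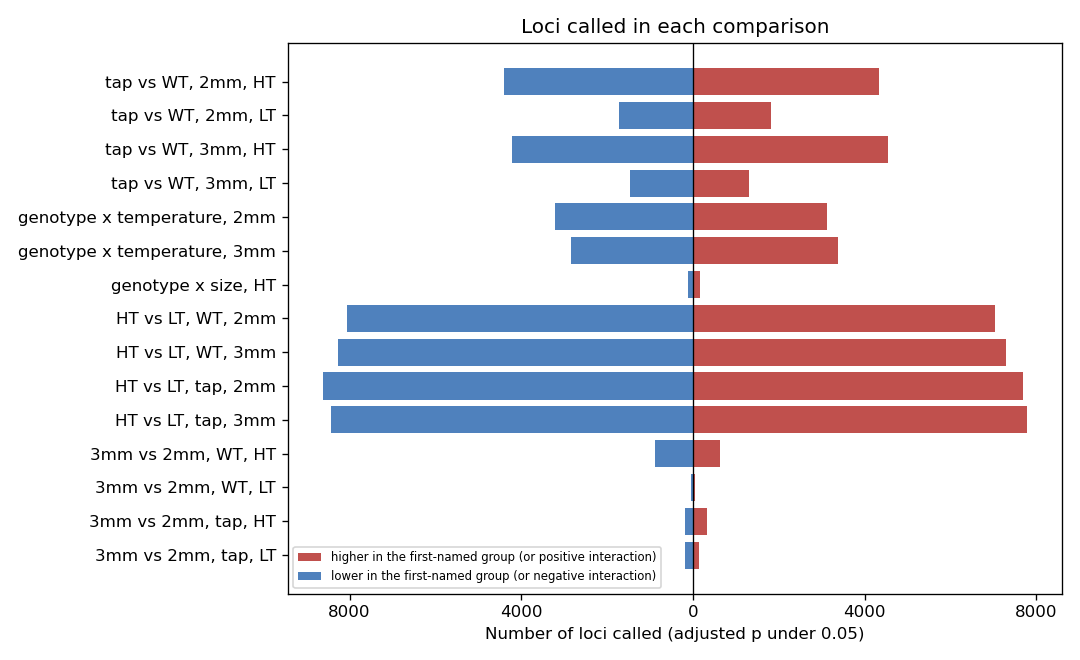
Number of loci called (horizontal axis, adjusted p under 0.05) in each of the 15 comparisons, with loci higher in the first-named group, or with a positive interaction, to the right and the others to the left. The temperature comparisons have 15104 to 16313 called loci, tap against WT has 8752 and 8776 at high temperature and 3542 and 2768 at low temperature, and the length comparisons have 87 to 1507.

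Loci called at 1 temperature were in part called at the other. Of the loci higher in tap at 2 mm, 584 were shared between the temperatures, where independent lists would share 333.3 (Fisher's exact test, p = 2.6e-49), and of the lower loci 391 were shared, where independent lists would share 321.7 (p = 1.4e-05). By the same exact test the shared loci at 3 mm numbered 515 higher, against 251.5 (p = 4.7e-68), and 417 lower, against 260.8 (p = 2.8e-25). A further 725 loci at 2 mm and 439 at 3 mm were called in opposite directions at the 2 temperatures, where independent lists would give 655.3 and 514.5. At 2 mm opposite calls were thus also above independence (1.11 times), near the 1.22 times of the shared lower loci. An excess over independent lists at 2 mm therefore does not by itself show agreement in direction. Across loci, which are not independent replicates, the log2 differences at high and low temperature correlated at r = 0.3 at 2 mm and 0.35 at 3 mm (Spearman's rho 0.07 and 0.11), while those at 2 mm and 3 mm correlated at 0.75 at high and 0.77 at low temperature (rho 0.69 and 0.68). These pairs of comparisons share no libraries. In all 4 comparisons of tap and WT, 317 loci were higher and 194 lower in tap. Given the loci shared by the lengths at each temperature, independence of the temperatures would give 121.4 and 113.9.

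The loci with large differences were in excess in a few stretches of the genome. Of 515 loci that differed at least 4-fold in the same direction at each length at high temperature, 70 lay in 3 of 131 windows of 5000 identifier numbers, namely numbers 0 to 4999 and 5000 to 9999 of chromosome 1 and 30000 to 34999 of chromosome 12. The windows were chosen after seeing the data. They held 22 of 225, 26 of 280 and 22 of 148 tested loci (adjusted binomial p = 2.6e-07, 5.3e-08 and 2.2e-10). At low temperature, in other libraries, 7.4% of the 653 loci in these windows differed at least 4-fold at each length, against 0.67% of the 22988 loci elsewhere (Fisher's exact test, p = 4.4e-31). Of these 48 loci, 22 were higher and 26 lower in tap.

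**Figure D3:**
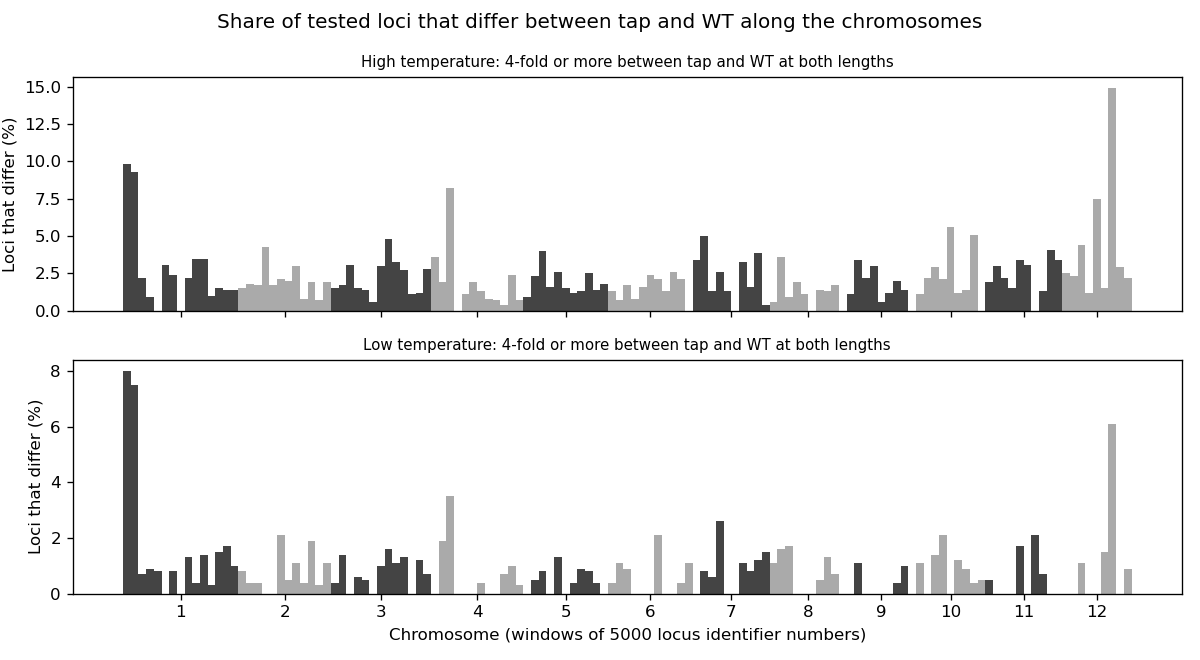
Share of tested loci (percent, vertical axis) that differed at least 4-fold between tap and WT at each length, in windows of 5000 identifier numbers along the 12 chromosomes, at high temperature (upper panel) and low temperature (lower panel), with shading that alternates between chromosomes. The tallest bars of the upper panel include 9.8% and 9.3% at the start of chromosome 1 and 14.9% on chromosome 12, and the same windows hold 8%, 7.5% and 6.1% in the lower panel.

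The dependence of the genotype difference on temperature was tested as an interaction. At 2 mm it was called for 6344 loci, and at 3 mm for 6235. At 2 mm, 3891 of these loci differed between tap and WT at high temperature without being called at low temperature, 985 were called at low temperature alone, 725 were called in opposite directions and 200 in the same direction with a larger difference at high temperature. At 3 mm the corresponding counts were 4205, 756, 439 and 199. The lengths shared 2021 positive and 1812 negative interactions, where independent lists would share 448.5 and 386.5, and 5 loci had interactions of opposite sign.

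Loci named for their interactions were of several kinds. LOC_Os06g33200 on chromosome 6 stood at 319 ± 52.2 CPM (n = 3) in tap and 0.103 ± 0.137 CPM in WT at 3 mm and high temperature, against 16 ± 2.14 and 0.853 ± 0.365 CPM at low temperature (interaction 7.3 ± 0.58 SE on the log2 scale, adjusted p = 1.6e-09). Of its 6 counts in WT at high temperature 5 came from 1 library, and without replicate 3 of that group the interaction was 9.07. LOC_Os04g27060 was at 20 ± 3.58 CPM in tap at 3 mm and high temperature and held 1, 5 and 5 counts in the other 3 groups of that length. LOC_Os07g41460 on chromosome 7 was at 9.87 ± 2.41 CPM in tap at 2 mm and high temperature, where WT had 0 counts, and at 0.294 ± 0.257 CPM in tap at low temperature. LOC_Os04g32080 was detected in WT at low temperature at 23.6 ± 1.35 CPM at 2 mm, with 1, 0 and 6 counts in tap at high temperature, WT at high temperature and tap at low temperature.

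Negative interactions at 2 mm were led by 2 loci whose genotype difference turned around. A difference between groups that the labels do not give cannot be told apart from genotype and temperature at these loci. LOC_Os01g17396 on chromosome 1 was at 9.54 ± 2.45 CPM in tap and 34 ± 7.03 CPM in WT at high temperature, but at 42.1 ± 7.31 CPM in tap and 0.562 ± 0.406 CPM in WT at low temperature (interaction -8.05 ± 0.47, adjusted p = 2.6e-10; -8.77 without replicate 1 of WT at low temperature). LOC_Os10g41550 on chromosome 10 was at 1.13 ± 0.479 CPM in tap and 9.88 ± 3.84 CPM in WT at high temperature, and at 16.6 ± 5.19 and 0.941 ± 0.523 CPM at low temperature (interaction -7.24 ± 0.69, adjusted p = 3.8e-07). At 3 mm and high temperature LOC_Os01g17396 was at 3.86 ± 1.33 CPM in tap and 2.09 ± 0.683 CPM in WT. LOC_Os10g41550 was there at 1.44 ± 0.541 and 1.45 ± 0.677 CPM. At 3 mm and low temperature LOC_Os01g17396 was at 41.7 ± 3.1 CPM in tap and 0.595 ± 0.385 CPM in WT. For LOC_Os10g41550 these levels were 16.2 ± 6.39 and 0.999 ± 0.471 CPM. The turn to a higher level in WT at high temperature was thus seen at 2 mm and not at 3 mm. The genotype difference of both loci was still larger at low than at high temperature at 3 mm. At 3 mm, LOC_Os09g26520 and LOC_Os05g11414 on chromosome 5 were lower in tap at each temperature, but by more at high temperature, with interactions of -7.29 ± 0.63 (adjusted p = 4e-09) and -6.96 ± 0.75 (adjusted p = 5.4e-08). Their tap libraries at high temperature held 2 counts and 1 count, all in replicate 3. Without that library the interactions were -10.04 and -8.91, so their sizes are not determined. The calls of LOC_Os04g32080 and LOC_Os04g27060 rest on groups near 0 counts, and leaving out replicate 3 of the 2 mm high-temperature tap libraries or replicate 2 of the 3 mm low-temperature WT libraries ended them (adjusted p = 1 and 0.99). The test against a 1.5-fold change called 1467 interactions at 2 mm and 1391 at 3 mm.

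Most tested loci differed between the high- and low-temperature libraries of each genotype. The share called was 63.8% to 69%. WT inflorescences had 15104 called loci at 2 mm, 7041 higher and 8063 lower at high temperature, and 15556 at 3 mm, 7285 higher and 8271 lower. Tap inflorescences had 16313 at 2 mm, 7688 higher and 8625 lower, and 16222 at 3 mm, 7780 higher and 8442 lower. With a minimum of 10 counts at high temperature, tap at 2 mm had 7732 higher and 7727 lower loci, so the excess of falls was gone there. Falls of more than 8-fold outnumbered rises, with 1487 falls and 168 rises in WT at 2 mm and 1554 falls and 407 rises in tap at 2 mm. At 3 mm the corresponding numbers were 1536 and 156 in WT and 1609 and 364 in tap. The deposited rows had been chosen on the low-temperature libraries, which limits what these counts of rises and falls can show. Separate processing of the 2 temperature sets cannot be told apart from temperature either, for these counts or for the loci named below.

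LOC_Os03g17610 on chromosome 3 rose in all 4 temperature comparisons, from 3 counts at low temperature to 38.4 ± 4.39 CPM (n = 3) at high temperature in WT at 2 mm, a ratio of 847 (95% counting interval 290 to 4110), and by ratios of 236 (128 to 493) in WT at 3 mm, 293 (148 to 680) in tap at 2 mm and 900 (308 to 4370) in tap at 3 mm. Its log2 change in tap moved from 8.12 to 8.91 at 2 mm and from 9.64 to 10.48 at 3 mm without replicate 3 at low temperature. In WT at 2 mm it moved from 9.55 to 10.39 without replicate 1 at low temperature. LOC_Os12g33280 on chromosome 12 rose to 17.9 ± 3.31 CPM in WT at 2 mm, a ratio of 170 (82 to 423), where 6 of its 7 counts at low temperature came from replicate 3 and its log2 change moved from 7.33 to 9.27 without that library. It rose to 15.8 ± 3.93 CPM in WT at 3 mm, a ratio of 340 (116 to 1650). LOC_Os02g24628 on chromosome 2 was named in tap at 2 mm with 26.6 ± 41 CPM, an SD above its mean, since 1387 of its 1504 counts came from 1 library, and with the 6 libraries alone it was not called (adjusted p = 0.059). Its log2 change was 8.98, and 5.85 and 12.09 without replicate 3 of the high- or of the low-temperature libraries. LOC_Os04g27060 rose in tap at 3 mm by a ratio of 259 (111 to 800), against 5 counts at low temperature. Its log2 change moved from 7.91 to 8.57 without replicate 2 of the low-temperature libraries.

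Among the falls, LOC_Os12g42390 on chromosome 12 had 0 counts in every high-temperature library and 39 ± 0.679 CPM in WT at 3 mm, 33.5 ± 3 CPM in tap at 2 mm and 30.9 ± 3.09 CPM in tap at 3 mm at low temperature, at least 757-fold, 654-fold and 593-fold lower. LOC_Os07g32761 and LOC_Os06g34570 fell from 64.2 ± 1.78 and 45.5 ± 1.1 CPM to 0 counts in WT at 2 mm, at least 1260-fold and 894-fold. LOC_Os04g46110 fell at least 876-fold in WT at 3 mm, LOC_Os02g43640 at least 568-fold in tap at 2 mm, and LOC_Os01g10460 at least 1340-fold in tap at 3 mm. There were 598 loci with at least 10 counts in every low-temperature WT library of 2 mm and at most 1 in every high-temperature library, and 9 with the opposite pattern. The choice of rows had left out loci near 0 counts in all low-temperature libraries, so these numbers cannot be set against each other. The tap and WT responses correlated across loci at r = 0.86 at 2 mm and 0.86 at 3 mm (Spearman's rho 0.74 and 0.75), and 694 and 591 loci responded in opposite directions, where independent lists would give 5187.1 and 5319.5. Separate processing of the temperature sets could move tap and WT alike, so this likeness cannot be credited to temperature alone. The test against a 1.5-fold change called 7532 and 7967 loci in WT at 2 mm and 3 mm and 8742 and 8850 in tap.

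Differences between 3 mm and 2 mm inflorescences were far fewer. In WT at high temperature 1507 loci were called, 627 higher and 880 lower at 3 mm, and at low temperature 87, of which 52 were higher and 35 lower. LOC_Os01g17396 fell from 34 ± 7.03 to 2.09 ± 0.683 CPM (n = 3) in WT at high temperature (log2 change -4.02 ± 0.32 SE, adjusted p = 2.4e-07), and LOC_Os08g06110 on chromosome 8 fell from 527 ± 94.9 to 58.7 ± 5.04 CPM (-3.17 ± 0.39, adjusted p = 1e-04). An unlabelled difference between the groups cannot be told apart from length at these loci. LOC_Os05g09740 rose from 2.73 ± 0.901 to 32.3 ± 18.7 CPM (3.56 ± 0.46, adjusted p = 0.00013) and LOC_Os04g41680 from 2.17 ± 0.799 to 22.7 ± 12.9 CPM (3.38 ± 0.48, adjusted p = 0.00018), but neither was called with the 6 libraries alone (adjusted p = 0.098 and 0.11). The WT count at high temperature was 758 without replicate 2 of 2 mm and 830 without replicate 2 of 3 mm. That at low temperature was 55, 55 and 4 without replicates 1, 2 and 3 of 2 mm and 24 without replicate 2 of 3 mm, and 194 with DESeq2. Its balance turned to 27 higher and 28 lower without replicate 2 of 2 mm, to 32 and 40 without replicate 1 and to 42 and 52 without replicate 3 of 3 mm.

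LOC_Os12g23200 and LOC_Os01g13870 were higher at 3 mm in WT at low temperature, by 1.51 ± 0.32 (adjusted p = 0.027) and 1.39 ± 0.27 (adjusted p = 0.02) on the log2 scale. LOC_Os01g50680 fell by 1.72 ± 0.33 (adjusted p = 0.029) and LOC_Os02g36810 by 1.35 ± 0.29 (adjusted p = 0.049). In that order, the adjusted p of these 4 loci was 0.14, 0.2, 0.2 and 0.28 without replicate 3 of 2 mm, 0.13, 0.069, 0.051 and 0.095 without replicate 2 of 2 mm, and 0.096, 0.072, 0.11 and 0.16 without replicate 1 of 3 mm. Without replicate 2 of 3 mm it was 0.14, 0.14 and 0.23 for LOC_Os12g23200, LOC_Os01g50680 and LOC_Os02g36810, without replicate 1 of 2 mm it was 0.076 for LOC_Os12g23200, and without replicate 3 of 3 mm it was 0.057 for LOC_Os01g13870. With the 6 libraries alone it was 0.37 for LOC_Os01g50680 and 0.13 for LOC_Os02g36810. For LOC_Os02g36810 it was also 0.059 with a replicate block, 0.052 with RLE size factors and 0.056 without a filter on low counts.

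Tap inflorescences differed between lengths at 523 loci at high temperature, 340 higher and 183 lower at 3 mm, and at 315 loci at low temperature, 132 higher and 183 lower. At high temperature LOC_Os07g06620 rose from 6.85 ± 2.62 to 18.5 ± 3.74 CPM (n = 3) and LOC_Os03g58600 from 22.1 ± 4.19 to 53.6 ± 2.19 CPM. LOC_Os02g13800 fell from 6.1 ± 1.42 to 1.15 ± 0.649 CPM and LOC_Os01g50680 from 13.2 ± 0.95 to 3.68 ± 0.831 CPM. At low temperature LOC_Os09g26520 rose from 1.56 ± 0.381 to 6.15 ± 1.31 CPM and LOC_Os08g41950 from 10.6 ± 7.07 to 41.3 ± 7.11 CPM, while LOC_Os11g38410 fell from 5.65 ± 1.71 to 1.15 ± 0.231 CPM and LOC_Os09g36140 from 7.91 ± 0.749 to 2.1 ± 0.426 CPM. LOC_Os08g41950 was not called with the 6 libraries alone (adjusted p = 0.17) and its log2 change moved from 1.96 to 2.59 without replicate 2 of 2 mm. Of the others, LOC_Os07g06620 was lost without replicate 3 of 2 mm (0.061), and LOC_Os01g50680 without replicates 1 and 3 of 2 mm (0.062 and 0.088) or of 3 mm (0.15 and 0.088).

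In the edgeR test against a 1.5-fold change, the length comparisons called 123 and 0 loci in WT and 2 and 15 in tap at high and low temperature. In WT at low temperature, where none was called, 1653 of 23658 loci had an unadjusted p under 0.05 in the test against no change. A share of 0.05 of the loci would have such a p with no difference at any locus.

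The tap counts moved with single libraries and with the libraries that the model pooled. At high temperature the count was 181, 1188 and 99 without replicates 1, 2 and 3 of 2 mm and 96, 2310 and 150 without replicates 1, 2 and 3 of 3 mm, and the 6 libraries alone gave 61, with 17 higher and 44 lower. The balance turned also without a filter on low counts, with 166 higher and 191 lower. At low temperature it was 107 and 168 without replicates 1 and 3 of 2 mm and 160, 131 and 172 without replicates 1, 2 and 3 of 3 mm, and 1208 with the 6 libraries alone. The 6 libraries alone thus reversed the order of the temperatures. The model of all libraries estimates a single spread per locus for both temperatures, while the median SE of tap against WT was 0.138 at high and 0.094 at low temperature. The counts for length in tap therefore do not rank the temperatures.

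Whether the length difference itself depended on genotype was tested at high temperature, where 301 loci were called, 176 positive and 125 negative. The balance turned under several alternatives. The counts were 19 positive and 32 negative with the 12 libraries alone and 125 and 133 without a filter on low counts. They were 184 and 310 without replicate 2 of 3 mm tap and 44 and 72 without replicate 3 of 2 mm tap. LOC_Os01g42190 on chromosome 1 rose with length in WT, from 2.31 ± 0.879 to 23.4 ± 8.67 CPM (n = 3), and stood at 13.4 ± 1.34 and 12.9 ± 0.864 CPM in tap (interaction -3.39 ± 0.37, adjusted p = 0.00011). LOC_Os05g09740 had an interaction of -3.05 ± 0.64 (adjusted p = 0.027), and its adjusted p was 0.21 with the 12 libraries alone, 0.051 without replicate 3 of 2 mm tap, 0.055 and 0.071 without replicates 1 and 3 of 3 mm tap, 0.068 and 0.07 without replicates 1 and 2 of 2 mm WT, and 0.052 and 0.066 without replicates 1 and 2 of 3 mm WT. LOC_Os01g17396 and LOC_Os06g36560 on chromosome 6 had interactions of 2.7 ± 0.45 (adjusted p = 0.0062) and 2.35 ± 0.39 (adjusted p = 0.0021). Against a 1.5-fold change, the test ended the calls of LOC_Os01g17396 (adjusted p = 0.067) and LOC_Os05g09740 (0.27). The count was 51 with the 12 libraries alone and 600 with DESeq2. Leaving out replicates 1, 2 and 3 of 2 mm tap gave 111, 601 and 116, replicates 2 and 3 of 3 mm tap 494 and 127, replicates 1 and 2 of 2 mm WT 189 and 116, and replicates 1 and 2 of 3 mm WT 185 and 141.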

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

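The tests of neighbouring loci, of a mislabelled sample, of the row filter, of separate processing and of all splits of the libraries but those for the length interaction were chosen only after the results were seen. The tests of the spread between libraries and of the splits for the length interaction were written beforehand.

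The difference between tap and WT itself differed between temperatures at 6344 loci at 2 mm and 6235 at 3 mm, and between lengths at high temperature at 301 loci, each by a test of the interaction. The log2 interactions of the loci named for the temperature test were 9.83 (LOC_Os04g32080), 8.49 (LOC_Os07g41460), -8.05 (LOC_Os01g17396) and -7.24 (LOC_Os10g41550) at 2 mm, and 9.76 (LOC_Os04g27060), 7.3 (LOC_Os06g33200), -7.29 (LOC_Os09g26520) and -6.96 (LOC_Os05g11414) at 3 mm. Those of LOC_Os04g32080 and LOC_Os07g41460 involve groups at 0 counts and that of LOC_Os04g27060 groups of 1, 5 and 5 counts. Those of LOC_Os09g26520 and LOC_Os05g11414 involve a group of 2 counts and of 1 count and were -10.04 and -8.91 without replicate 3 of 3 mm tap at high temperature. That of LOC_Os06g33200 involves a group of 6 counts and was 9.07 without replicate 3 of 3 mm WT at high temperature. None of these 6 is a measure of size. The interactions named for the length test were 2.7 (LOC_Os01g17396), 2.35 (LOC_Os06g36560), -3.39 (LOC_Os01g42190) and -3.05 (LOC_Os05g09740).

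Other splits of the same libraries were used to ask how often chance gives as many loci. Of 60 splits drawn from 200, 1 split, the real 1, called as many loci for the temperature interaction at each length, with 6538 loci in the real split against 3425 in the highest other at 2 mm and 5587 against 3387 at 3 mm. Each of these highest splits kept the genotype labels intact at 1 temperature, so it still holds the genotype difference there. The other splits mix tap and WT libraries, so they do not show what chance gives for an interaction where a genotype difference is present, and by them chance is not excluded. For the length interaction 4 of 60 splits called as many as the 51 loci of the real split, and chance is not excluded there either. The highest called 10735 and kept the genotypes apart at each length with the labels of 1 length exchanged, which makes it a test of the genotype difference and points to that structure of the samples. The 12 comparisons of 3 against 3 libraries allow 10 splits each, too few for a share under 5%. For tap against WT, with 1 split in 10 as large, the real and highest other counts were 7069 and 0 at 2 mm and 6579 and 0 at 3 mm at high temperature, and 5611 and 0 and 3570 and 0 at low temperature. For temperature they were 15206 and 0, 15114 and 0 in WT and 16101 and 0, 15976 and 0 in tap at 2 mm and 3 mm. For length they were 1181 and 2 in WT at high temperature, 102 and 64 in WT at low temperature, 61 and 87 in tap at high temperature, where 2 splits called as many, and 1208 and 0 in tap at low temperature.

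Among the 70 loci without high-temperature values, which enter no comparison of the report, 67 could be tested in a model of the 12 low-temperature libraries. Tap and WT differed at 11 of them at 2 mm, 5 higher and 6 lower, and at 10 of them at 3 mm, 5 higher and 5 lower. Over all 23100 loci of that model the counts were 5114 and 4328, a larger share.

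The first pattern weighed is the closeness of stable tap and WT differences on chromosomes 1 and 12. Reads of a single line lost in mapping would shift nearly all of these loci the same way, but 42.9% of the 70 loci in the 3 windows were lower in tap. This argues against a loss in the same line throughout. Losses in tap at some loci and in WT at others would give such a mix and were not tested. A sample with the wrong genotype label is argued against by 0 of 24 libraries lying nearer to the other genotype over loci of these windows chosen in the libraries of the other temperature. Libraries exchanged between the lengths of a genotype could not be seen by this test. Among 225 loci called at high temperature in the windows, the log2 differences at high and low temperature correlated at 0.89, against 0.54 among 5508 such loci elsewhere. The windows were chosen for large differences at high temperature, and a wider range of differences can raise a correlation by itself. Segments from another strain in either line are a candidate explanation that these correlations do not decide. A local effect of a single mutated locus, which was not tested, would cover the windows of at most 1 of the 2 chromosomes.

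The second pattern is that tap and WT differed at more loci at high than at low temperature. The gap was 8752 against 3542 loci at 2 mm and 8776 against 2768 at 3 mm, but 7069 against 5611 and 6579 against 3570 in models of the 6 compared libraries alone, so its size depends on which libraries the model pools. A smaller spread between high-temperature libraries could raise the number of calls, but over 16217 loci of at least 5 CPM, with error removed, the spread of true differences at high temperature was 1.43 ± 0.08 (jackknife SE over chromosomes) times that at low temperature at 2 mm and 1.59 ± 0.08 times at 3 mm, which argues against it. The median SE was in fact larger at high temperature, 0.138 against 0.094. A dependence of the mutant on temperature, which the design names, stays open as a hypothesis, as does any unlabelled difference in growth between the lines within the high-temperature set.

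The third pattern is the excess of large falls at high temperature. The choice of rows on low-temperature totals could produce it by leaving out loci transcribed at high temperature alone. With the same minimum of 10 counts in the libraries of each temperature, 685 falls and 168 rises of more than 8-fold were left in WT at 2 mm (4.08 times as many, 95% binomial interval 3.44 to 4.86), 729 and 156 in WT at 3 mm (4.67, 3.93 to 5.59), 757 and 407 in tap at 2 mm (1.86, 1.65 to 2.1) and 792 and 364 in tap at 3 mm (2.18, 1.92 to 2.47). Over all loci the ratios were 8.85, 9.85, 3.82 and 4.42, so the choice of rows can account for part of the excess, but these values argue against it as the whole cause. Among the few loci of at least 1 CPM in the lower group, falls and rises were 69 and 33, 79 and 31, 88 and 79, and 89 and 76 in the same order, close to balance in tap. Separate processing of the temperature sets cannot be told apart from temperature, because 0 sets of columns named alike hold both temperatures.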

How the results depend on the processing

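Gene lists and their 3 alternatives were not run, for want of names. The minimum of 10 counts at high temperature, the removal of 2 chromosome segments and the minimum of 5 CPM for counts were chosen after seeing the data. RLE size factors and the absence of a low-count filter left the 15 counts within 1.5 times of their main values (without the filter, length in tap at high temperature turned from 340 higher and 183 lower to 166 and 191), as did the minimum of 10 counts and the removal of segments where they applied. The replicate numbers were not taken to pair the libraries, because the labels do not say what a number means. The deviations of same-numbered libraries from their group means correlated at -0.13 to 0.16 over 84 pairs, with 8 pairs over 0.1. For different numbers the range was -0.23 to 0.26, with 5 of 168 pairs over 0.1. Of 24 libraries, 13 lay closest to their own number, where chance gives about 8. These values lean toward some pairing and do not exclude it. With a replicate block the counts were 1.00 to 1.18 times the main counts, for example 8759 for tap against WT at 2 mm and high temperature, and the block ended the call of 1 named locus, LOC_Os02g36810, for length in WT at low temperature (adjusted p = 0.059), which RLE size factors (0.052) and the absence of a filter (0.056) ended too.

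The test against a 1.5-fold change, which asks for a larger effect, lowered the counts to 1650, 589, 2033 and 434 for tap against WT (2 mm high, 2 mm low, 3 mm high, 3 mm low), 1467, 1391 and 7 for the interactions with temperature (2 mm, 3 mm) and length, and 7532, 7967, 8742 and 8850 for temperature (WT 2 mm, WT 3 mm, tap 2 mm, tap 3 mm). For length, where it was not among the alternatives fixed beforehand, it gave 123, 0, 2 and 15 (WT high, WT low, tap high, tap low), against 1507, 87, 523 and 315. With the compared libraries alone the count was 5611 for tap against WT at 2 mm and low temperature, 51 for the length interaction, and 61 and 1208 for length in tap at high and low temperature. DESeq2 gave 600 for the length interaction, 194 for length in WT at low temperature and 1055 for length in tap at high temperature. The minimum of 5 CPM gave 47 for length in WT at low temperature, and correlations of the temperature responses of 0.84 and 0.85. Except where a sentence names construction, the cause was not tested.

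Leaving out single libraries moved the counts to 6729 to 8848, 2414 to 2743, 6980 to 8767 and 1791 to 2393 for tap against WT in the order above, 5191 to 6727, 5127 to 6553 and 111 to 601 for the interactions, 14141 to 14261, 14432 to 14847, 15280 to 15811 and 15281 to 15566 for temperature, and 758 to 1765, 4 to 94, 96 to 2310 and 107 to 218 for length (WT high, WT low, tap high, tap low). The length results are therefore the least stable. Of 60 named changes, 46 kept their direction and call under every alternative run and 14 lost their call under at least 1; none of the 60 reversed. All 8 overlaps of tap and WT calls in the same direction stayed above independence at an adjusted p under 0.01. At that threshold, calls in opposite directions at the 2 temperatures were also above independence at 2 mm (307 against 247). At 3 mm they were below it (149 against 183.7). Where a group held 3 counts or fewer, depth leaves the size of a fold open.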

Other observations

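The tests of neighbouring loci and of a scaled response were chosen only after the results were seen, the latter after a plain regression slope at 2 mm had been looked at.

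Outside the 3 windows on chromosomes 1 and 12, loci that differed between tap and WT at high temperature were direct neighbours more often than in shuffles, although most had no such neighbour. Among 320 loci that were at least 4-fold higher in tap at each length, 30 pairs were direct neighbours among the tested loci, against a mean of 4.41 and a maximum of 12 in 1000 shuffles (permutation p = 0.001, the smallest these shuffles can give). Among 122 loci at least 4-fold lower, 11 pairs were neighbours, against a mean of 0.68 and a maximum of 4 (permutation p = 0.001, again the smallest possible). LOC_Os08g05960 and LOC_Os08g05970, named above, lie side by side. Neighbours can be copies of each other, and reads divided between copies were not examined.

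The values of LOC_Os08g06110, chosen after they were seen, varied with genotype, length and temperature, and no test joined the 3. It stood at 671 ± 5.79 and 735 ± 12.5 CPM in tap at low temperature at 2 mm and 3 mm, against 105 ± 46.8 and 110 ± 70 CPM in WT, whereas at high temperature tap was at 197 ± 38.2 and 96.6 ± 26.3 CPM and WT at 527 ± 94.9 and 58.7 ± 5.04 CPM. LOC_Os01g17396 and LOC_Os10g41550 were likewise highest in tap at low temperature and in WT at 2 mm and high temperature, a likeness also seen after the fact. A difference between groups that the labels do not give could not be told apart from effects of genotype, length and temperature at these loci. The labels do not exclude such a difference for the other comparisons of groups either.

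A hypothesis was that tap shows the WT temperature response on a larger scale. Over 16217 loci of at least 5 CPM, the slope of the tap on the WT response, with the WT response at the other length as a second measurement, was 0.928 ± 0.01 (jackknife SE over chromosomes) at 2 mm and 0.904 ± 0.009 at 3 mm. The slope of the WT on the tap response, with tap at the other length as a second measurement, was 0.819 ± 0.016 and 0.84 ± 0.013. Responses particular to a genotype at a locus lower each slope, whatever the scale, so these values do not decide whether the tap response is larger. Counts of interactions depended on how loci were selected. Among loci called for temperature in WT at the other length, the interaction was called toward a smaller response in tap at 2264 loci and toward a larger response at 1309 at 2 mm, and at 2401 and 1073 loci at 3 mm. Among loci called in tap at the other length, it was called toward a smaller response in tap at 964 loci and toward a larger response at 2824 at 2 mm, and at 1063 and 2672 loci at 3 mm. The question stays open.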
